A study of Glycine max with 36 samples.

How the data were processed

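The series holds 36 RNA sequencing samples of soybean leaves, 3 in each of 12 groups made of 3 lines (W82, DR1-136 and DR1-107), 2 treatments (buffer or chitin) and 2 time points (12 and 24 h). Per the labels' protocols, seedlings grew at 23 °C with 16 h of light and 8 h of dark, and chitin at 100 µmol/L was given in 15 mmol/L sodium phosphate. Reads were aligned with TopHat and compared with Cuffdiff, per the submitters' processing notes. Their versions, the genome build, the annotation and any filters are not given in the sources used here. The authors deposited tables of pairs of groups with an FPKM value per group, which per the file headers is scaled by gene length and by the number of mapped fragments, pooled over the samples of the group. The authors' log2 fold change in the deposited tables is that of the second over the first group, and its sign was turned so that the group named first in the text is the numerator. The p-value and the adjusted p-value are those of the authors' Cuffdiff test, as deposited. Values per sample, counts and test statistics were not used here, so no SD is given and the depth per sample is unknown.

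Columns were assigned to groups through the letter that the labels give to each sample. This matched both columns of 11 tables, 6 at 12 h and 5 at 24 h. Another 11 tables each hold a column whose letter no sample carries. Those 11 columns and their tables were used in no step. At 24 h the pairs of letters in the tables do not follow the order of the 12 h pairs, and read by analogy with 12 h they would give some letters to other groups than the labels do. The labels were kept, and the conflict applies to every 24 h value. Each table was scaled separately by the authors, so tests were made within a table. Each table lists 47946 genes on chromosomes 1 to 18 and scaffolds, 35450 with a Pfam accession and 23385 with a GO accession. Recomputed log2 ratios of FPKM differed from the deposited ones by at most 5.01e-05. The deposited adjusted p equals the Benjamini-Hochberg value over genes with p below 1 within 3.26e-05, and these genes are called tested. The smallest p is 5e-05.

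The rules for tests, lists and named genes were set before the data were examined. A gene was called at a deposited adjusted p under 0.05. Named are the 6 largest rises and the 6 largest falls per comparison among called genes with a domain, above 0 in both groups and at 5 FPKM or more in either, and up to 2 called members per list and direction with the smallest adjusted p, of which the text gives a selection made after their values were seen. The reference table of gene symbols matched 0 identifiers. Genes are therefore described by Pfam domain, whose meanings are background knowledge, and at most 2 identifiers that rose and 2 that fell are printed per comparison. The 20 gene lists had been fixed as patterns of product descriptions. They were translated to Pfam domains after the data were seen and before any result of a list, which makes some of them wider or narrower than planned. The ethylene list became the AP2 domain, so results for it are about the AP2/ERF family and do not show a change of ethylene signalling. The clock list lost LHY. Lists were tested per direction with Fisher's exact test, two-sided, against the other tested genes, with Benjamini-Hochberg adjustment over 240 tests at 12 h. This test treats genes as independent. List members may be regulated together, so its p-values do not measure the strength or reproducibility of a change between groups. List medians of log2(FPKM + 0.1) changes, which understate the change of low genes, were set against 10000 random lists matched on expression in 20 bins, for genes with FPKM of at least 1 in either group. Beside these, the count adjusted over the list alone is given.

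The difference of chitin response is the genotype change in chitin minus that in buffer. The design had planned standard errors from deposited test statistics. As the tables used here hold none, each standard error was derived from the deposited p-value as the log2 change divided by the normal quantile. For p above 0.95 it was at least the running median of 201 genes of like expression. At the smallest p that quotient is only an upper bound, and it was limited to the 90th percentile of 201 neighbouring genes. This limit was not part of the first form of the rule. It was added when simulated data were recovered poorly, after the first counts from the real data had been seen, and its percentile was chosen among 4 on simulated data alone. For DR1-136 the first form gave 0 genes and the final form 6, so that count depends on the rule. Shared controls were handled with 100 simulations of unchanged groups. Similarity of groups was taken over genes with FPKM of at least 10.

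The difference of chitin response, the list test and the handling of shared controls were tested on simulated data. The last 2 were tested only for the comparisons with W82 in chitin at 12 h. Other steps were not tested this way. Of 200 genes with a planted response difference for DR1-107, 71.5% were recovered at a log2 difference of 3, 29% at 2 and 0 at 1 among 29203 genes, with false shares of 5.92% and 6.45% of calls at 3 and 2, above the nominal level. For DR1-136 the recovered shares were 44.5%, 3.5% and 0 among 7073 genes, with a false share of 4.30% at 3. The simulated p-values followed the same normal model that the standard errors assume, and few genes were planted. These false shares therefore do not measure the error rate of the calls in the real data. In the simulated chitin comparisons at 12 h the planted list was found with 0 false lists, among 33137 genes for DR1-107 and 33297 for DR1-136. A planted covariance of 0.160 between the chitin comparisons was estimated as 0.151 over 31096 genes. Alternatives were an adjusted p under 0.01, a minimum absolute log2 change of 1, FPKM of at least 1, a pseudocount of 1, median centring, a recomputed adjustment and leaving out genes at 0. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.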

Results

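RNA sequencing was used to measure transcript levels in first trifoliate leaves of soybean (Glycine max) seedlings given chitin, the polymer of fungal cell walls, through the cut stem. Williams 82 (W82) was the non-transgenic recipient cultivar. DR1-136 and DR1-107 carry GmDR1 behind different promoters, which the labels call weak and strong. Seedlings took up 0.5 mL of a phosphate buffer at pH 6.5 with or without chitin at 100 µmol/L, and leaves were taken at 12 or 24 h. The 36 samples form 12 groups of 3 samples. The labels do not say whether the 3 came from separate plants, so p-values measure only the spread between these samples, which may be technical. The title names the question, whether the receptor encoded by GmDR1 changes the levels of nucleotide-binding leucine-rich repeat (NLR) receptors. Values are the authors' FPKM from tables of group pairs, 1 value per group and without a spread. They cover 47946 genes of chromosomes 1 to 18 and unplaced scaffolds, with chromosomes 19 and 20 not analysed here. The files pair gene identifiers with Pfam protein domains and not with names, so genes are described by domain and few identifiers are printed.

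GmDR1 was read first, since it checks the labels. Its gene model was taken beforehand from knowledge of the study as Glyma.10G094800 (chromosome 10, 13425705 to 13426234, build not given in the sources used here). In buffer at 12 h it was at 3.12 FPKM in the group labelled DR1-107 and listed at 0 in the group labelled W82 in the authors' deposited table (Cuffdiff adjusted p = 0.00033). The group labelled DR1-136 in buffer was also listed at 0 in the authors' deposited table. The lowest 1% of FPKM above 0 in that group reached 1.60, so a low level could be missed. In chitin the order was opposite to the labels. The authors' deposited table gave 1.28 FPKM in the group labelled DR1-107 and 5.62 in the group labelled W82, a log2 change of -2.13 (Cuffdiff adjusted p = 0.00477). The group labelled DR1-136 in chitin was at 1.86 FPKM against 5.82 in W82 in the authors' deposited table, which did not pass the test (log2 -1.65, Cuffdiff adjusted p = 0.0936). Within the group labelled W82, GmDR1 was at 4.92 FPKM in chitin and listed at 0 in buffer in the authors' deposited table (Cuffdiff adjusted p = 0.000378). In the group labelled DR1-107 it was at 1.27 in chitin and 3.59 in buffer in the authors' deposited table (log2 -1.50, Cuffdiff adjusted p = 0.0356). At 24 h it was listed at 0 in every group. All of these but DR1-107 in chitin had at most 5781 genes above 0, so their zeros say little about GmDR1. Because GmDR1 went against the labels in chitin, all directions below are between groups as labelled.

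The groups differed in how many genes were listed above 0. At 12 h in buffer this number was 35138 in W82, 40999 in DR1-107 and 15738 in DR1-136. In chitin it was 40951 in W82, 40418 in DR1-107 and 40639 in DR1-136. Read depth is unknown from FPKM. As a trace of it, the lowest 1% of FPKM above 0 reached 1.60 in DR1-136 in buffer and 0.0263 in W82 in buffer, against 0.0117 in W82 in chitin. Correlations of log2 FPKM, from tables scaled separately, were taken across 6574 genes, which are not independent replicates. Pearson's r was 0.984 between DR1-107 in buffer and W82 in chitin and 0.975 between DR1-136 and W82 in chitin. W82 and DR1-136 in buffer had r of 0.796 with each other and stood apart from the other 4 groups. For W82 in buffer r was 0.606 with DR1-107 in buffer, 0.659 with W82, 0.665 with DR1-136 and 0.713 with DR1-107 in chitin. For DR1-136 in buffer r was 0.529 with DR1-107 in buffer, 0.568 with W82, 0.589 with DR1-136 and 0.637 with DR1-107 in chitin.

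**Figure D1:**
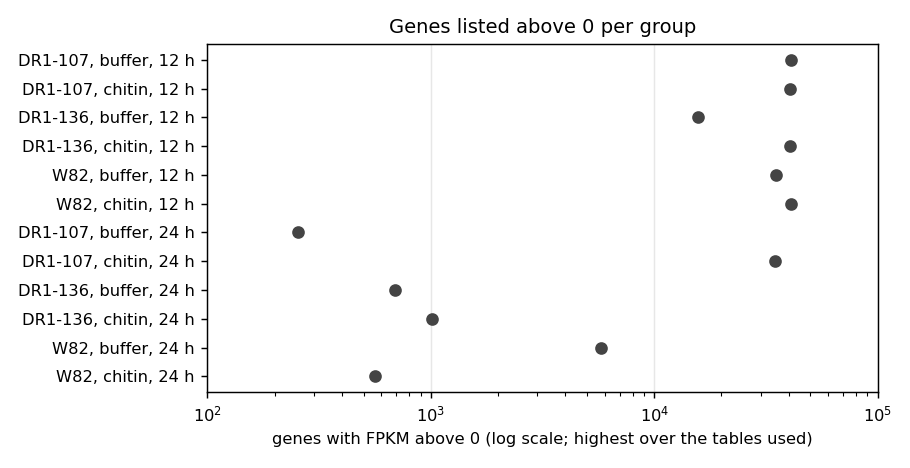
Number of genes with FPKM above 0 (log axis, highest value over the tables used) in each of the 12 groups. At 24 h the group labelled DR1-107 in chitin had 34888 genes above 0 and the other groups at most 5781.

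In chitin at 12 h, several lists were over-represented among the genes called higher in the group labelled DR1-107 than in W82. They included WRKY factors, NLR receptors, AP2/ERF genes and the jasmonate and salicylate lists. Cell division genes were over-represented among those called lower. Secondary wall genes were called both ways. Cuffdiff called 6098 of 33251 tested genes in the authors' deposited table, 3114 higher and 2984 lower. Here and below, the largest changes are those among called genes with a domain, above 0 in both groups and at 5 FPKM or more in either. The largest rise was that of Glyma.11G003500 (chromosome 11, 256058 to 259075), which has the domain of pyridoxal phosphate-dependent enzymes. It was 46.9-fold higher in the authors' deposited table (log2 5.55, Cuffdiff adjusted p = 0.000757). Next came Glyma.11G059100 (chromosome 11, 4460356 to 4462346), with a reticulon domain, at 6.17 against 0.153 FPKM in the authors' deposited table (Cuffdiff adjusted p = 0.00392). A pair of genes with TIFY and Jas motifs, the mark of the JAZ repressors of jasmonate signalling, were 19.4-fold and 16.9-fold higher in the authors' deposited table (Cuffdiff adjusted p = 0.000757 for each). The largest fall was that of Glyma.15G105900 (chromosome 15, 8273267 to 8276604), with a triose-phosphate transporter domain, from 5.26 to 0.0975 FPKM in the authors' deposited table (Cuffdiff adjusted p = 0.00894). The peroxidase Glyma.14G053700 (chromosome 14, 4231165 to 4234628) fell from 6.82 to 0.201 in the authors' deposited table (Cuffdiff adjusted p = 0.000757). Genes with a glutaredoxin domain and with a haloacid dehalogenase-type hydrolase domain were 26.9-fold and 22.8-fold lower in the authors' deposited table (Cuffdiff adjusted p = 0.000757 for each). A gene with the gamma-thionin domain of plant defensins was 19.8-fold lower in the authors' deposited table (Cuffdiff adjusted p = 0.00596). A gene with both expansin domains, whose proteins loosen cell walls, was 17.6-fold lower in the authors' deposited table (Cuffdiff adjusted p = 0.000757).

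Gene lists in this comparison were tested with Fisher's exact test, two-sided, against the other tested genes. Here and below, that test treats genes as independent, so its p-values do not measure the spread between samples. Of all tested genes 9.37% were called higher and 8.97% lower. Of 141 WRKY transcription factors, 54 were higher and 4 lower (adjusted p = 2.33e-18 for higher calls by Fisher's exact test). Adjusted over the list alone, 65 were higher and 5 lower. The leading WRKY gene was at 14.1 FPKM against 2.13 in the authors' deposited table, and a member called lower was at 4.17 against 7.28. Of 220 NLR genes, defined by the NB-ARC domain, 51 were higher and 10 lower, and 54 and 10 adjusted over the list alone. Higher calls exceeded the background (adjusted p = 1.85e-08) and lower calls were fewer than it (adjusted p = 0.0468), by Fisher's exact test. An NB-ARC gene rose from 7.37 to 57.7 FPKM and another fell from 0.883 to 0.197 in the authors' deposited table. Calcium-binding EF-hand genes had 50 higher and 6 lower of 185 (adjusted p = 1.27e-10 by Fisher's exact test; 57 and 9 adjusted over the list alone). AP2/ERF genes, the ethylene list, had 55 higher and 14 lower of 227 (adjusted p = 6.96e-10 by Fisher's exact test; 61 and 20 adjusted over the list alone). The jasmonate list had 26 higher and 6 lower of 73 (adjusted p = 1.31e-08 by Fisher's exact test; 27 and 6 adjusted over the list alone). Of 21 genes of the salicylate list, 10 were higher and 0 lower (adjusted p = 4.1e-05 by Fisher's exact test). The numbers were 13 and 0 at an unadjusted Cuffdiff p under 0.05, and 12 and 0 adjusted over the list alone. The leading members carry the domain of the CBP60 calmodulin-binding proteins, which include regulators of salicylate synthesis. The first of them was at 11.6 FPKM against 1.85 in W82 in the authors' deposited table. Protease inhibitors had 12 higher and 4 lower of 33 (adjusted p = 0.000123 by Fisher's exact test; 14 and 5 adjusted over the list alone). Genes for water stress and abscisic acid had 42 and 15 of 214 (adjusted p = 2.91e-05 by Fisher's exact test; 49 and 16 adjusted over the list alone). Photosynthesis genes had 15 and 1 of 77 (adjusted p = 0.0167 by Fisher's exact test; 17 and 1 adjusted over the list alone). Lower calls were fewer than the background for WRKY factors (adjusted p = 0.0212), calcium (adjusted p = 0.0138) and photosynthesis (adjusted p = 0.0392), by Fisher's exact test. Neither photosynthesis result passed Fisher's exact test among calls at adjusted p under 0.01 (adjusted p = 0.557 for higher and 0.0930 for lower calls).

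Cell division and chromatin genes had 4 higher and 44 lower of 118 in this comparison (adjusted p = 2.53e-15 for lower calls by Fisher's exact test; 4 and 52 adjusted over the list alone). A histone gene fell from 9.68 to 2.23 FPKM in the authors' deposited table. Epidermis and guard cell genes had 5 and 19 of 78 (adjusted p = 0.000223 for lower calls by Fisher's exact test; 6 and 23 adjusted over the list alone). Pathogenesis-related proteins had 11 and 22 of 108 (adjusted p = 0.00106 for lower calls by Fisher's exact test; 16 and 24 adjusted over the list alone), and a PR-1-type gene fell from 2.51 to 0.447 FPKM in the authors' deposited table. Some lists moved both ways. The lignin and secondary wall list had 16 higher and 29 lower of 80 (adjusted p = 0.0114 and 4.85e-10 by Fisher's exact test; 17 and 31 adjusted over the list alone). A laccase was 7.98-fold higher and a cellulose synthase gene fell from 162 to 25.5 FPKM in the authors' deposited table. Receptor-like kinases and proteins had 105 higher and 97 lower of 618 (adjusted p = 2.7e-08 and 7.6e-07 by Fisher's exact test; 116 and 109 adjusted over the list alone). Redox and detoxification genes had 40 and 37 of 277 (adjusted p = 0.0203 and 0.0401 by Fisher's exact test; 43 and 43 adjusted over the list alone). Heat shock genes had 23 and 10 of 277, fewer lower calls than the background (adjusted p = 0.00277 by Fisher's exact test; 21 and 9 adjusted over the list alone). Among calls at adjusted p under 0.01, the higher redox calls (adjusted p = 0.331) and the deficit of lower heat shock calls (adjusted p = 0.108) no longer passed Fisher's exact test. Against random lists matched on expression, the median log2 change of the redox list lay at percentile 46.1, that of phenylpropanoid and isoflavonoid genes (-0.41) at 0.03 and that of chitinases and glucanases (-0.17) at 0.13. Neither direction passed Fisher's exact test for chitinases and glucanases (15 higher and 11 lower of 90), phenylpropanoid and isoflavonoid genes (1 and 5 of 26) or storage proteins (3 and 3 of 18). The same held for clock genes (0 and 2 of 21, with 2 and 4 at an unadjusted Cuffdiff p under 0.05). Outside that list, the 3 copies of LHY analysed here, a clock gene, were all called lower, at 33.7 against 62.3, 5.24 against 9.27 and 2.47 against 5.17 FPKM in the authors' deposited table (Cuffdiff adjusted p = 0.00296, 0.0173 and 0.00296). A different hour of harvest was not tested for this comparison. Nor was it for the chitin response of DR1-107, where all 3 copies were called lower too. A different share of mesophyll cells was not tested for either comparison and stays open.

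**Figure D2:**
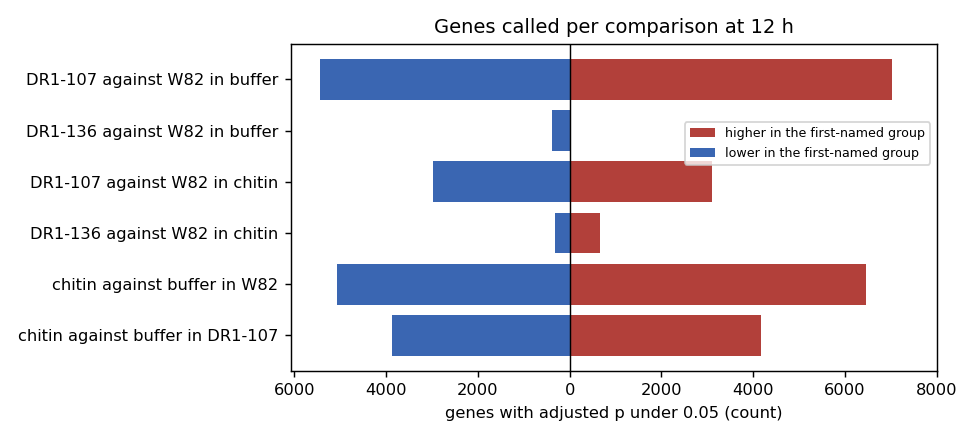
Number of genes with Cuffdiff adjusted p under 0.05 in each comparison at 12 h, higher (right) or lower (left) in the first-named group. The comparisons with W82 in buffer that were not against DR1-136 had 12477 and 11536 called genes.

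In chitin-treated leaves of the group labelled DR1-136, NLR genes and receptor-like kinases were over-represented among the genes called higher than in W82. Cuffdiff called 992 of 33388 tested genes in the authors' deposited table, 670 higher and 322 lower. Of 226 NLR genes, 42 were higher and 0 lower, against 2.01% called higher among all tested genes (adjusted p = 9.96e-26 by Fisher's exact test). At an unadjusted Cuffdiff p under 0.05, 93 NLR genes were higher and 3 lower, and 64 and 1 were called when adjusted over the list alone. An NLR gene with an additional TIR domain, Glyma.03G053500 (chromosome 3, 7150987 to 7174389), was at 2.35 FPKM against 0.0782 in the authors' deposited table (Cuffdiff adjusted p = 0.00376). The next NB-ARC gene was at 0.966 against 0.173 in the authors' deposited table (Cuffdiff adjusted p = 0.00376). The median log2 change of the 204 NLR genes with FPKM of at least 1 in either group was 0.43, above all 10000 random lists matched on expression. Among the other lists over-represented among higher calls there, the median was at percentile 41.7 of random lists for jasmonate, 67.1 for redox and 93.8 for water stress genes. Receptor-like kinases and proteins had 46 higher and 3 lower of 631 (adjusted p = 2.82e-12 by Fisher's exact test; 69 and 12 adjusted over the list alone). A gene with a wall-associated kinase domain was 4.34-fold higher in the authors' deposited table. WRKY factors had 17 and 0 of 141 (adjusted p = 5.05e-08 by Fisher's exact test; 26 and 0 adjusted over the list alone), with 40 and 0 at an unadjusted Cuffdiff p under 0.05. A WRKY gene was 4.63-fold higher in the authors' deposited table.

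The largest rise in DR1-136 in chitin was that of the peroxidase Glyma.09G284400 (chromosome 9, 50342735 to 50344411), from 0.773 to 8.62 FPKM in the authors' deposited table (log2 3.48, Cuffdiff adjusted p = 0.00376). A cellulose synthase gene was 10.7-fold higher in the authors' deposited table. A dirigent gene, of a family that guides lignan coupling, rose from 8.54 to 65.7 FPKM in the authors' deposited table. The largest falls were those of a glutathione S-transferase, Glyma.07G139900 (chromosome 7, 16436062 to 16437413), and of a SWEET-family sugar transporter, Glyma.06G166800 (chromosome 6, 13866484 to 13868782). The first fell from 26.3 to 0.935 FPKM and the second from 8.13 to 0.306 in the authors' deposited table (Cuffdiff adjusted p = 0.00376 for each). Redox and detoxification genes had 23 higher and 5 lower of 276 (adjusted p = 1.3e-07 for higher calls by Fisher's exact test; 29 and 6 adjusted over the list alone). Ethylene genes had 17 and 1 of 227 (adjusted p = 2.84e-05; 26 and 10 adjusted over the list alone) and calcium signalling genes 14 and 1 of 182 (adjusted p = 0.000114; 19 and 2 adjusted over the list alone), by Fisher's exact test. Salicylate genes had 5 and 0 of 21 (adjusted p = 0.00024 by Fisher's exact test; 7 and 0 adjusted over the list alone), with 7 and 0 at an unadjusted Cuffdiff p under 0.05. Jasmonate genes had 6 and 1 of 72 (adjusted p = 0.0115; 8 and 1 adjusted over the list alone) and water stress genes 10 and 1 of 213 (adjusted p = 0.0319; 12 and 5 adjusted over the list alone), by Fisher's exact test. Protease inhibitors went both ways, with 4 higher and 5 lower of 38 (adjusted p = 0.0207 and 0.000156 by Fisher's exact test; 6 and 5 adjusted over the list alone). A Kunitz inhibitor was 10.1-fold higher in the authors' deposited table. Cell division genes had 0 higher and 6 lower of 118 (adjusted p = 0.00397 for lower calls by Fisher's exact test), with 0 and 35 at an unadjusted Cuffdiff p under 0.05, and 0 and 14 adjusted over the list alone. Heat shock genes had 0 and 4 of 278, fewer higher calls than the background (adjusted p = 0.0227 by Fisher's exact test). Their numbers were 7 and 18 at an unadjusted Cuffdiff p under 0.05, and 0 and 2 adjusted over the list alone. Among calls at adjusted p under 0.01, Fisher's exact test was no longer passed by water stress (adjusted p = 0.525), cell division (adjusted p = 0.675), lower calls of protease inhibitors (adjusted p = 0.331) or heat shock genes (adjusted p = 0.183). Neither direction passed Fisher's exact test for pathogenesis-related proteins (3 and 4 of 109), lignin (4 and 2 of 80), epidermis (2 and 2 of 80), storage proteins (2 and 1 of 18) or chitinases and glucanases (5 and 0 of 91, with 8 and 3 at an unadjusted Cuffdiff p under 0.05). The median log2 changes of pathogenesis-related proteins (-0.16) and lignin (-0.19) nevertheless lay below all 10000 random lists matched on expression. Those of photosynthesis (-0.17) and phenylpropanoid genes (0.14) were at percentile 0.21 and 98.1. Cuffdiff called 0 of 27 phenylpropanoid, 0 of 74 photosynthesis and 0 of 21 clock genes. At an unadjusted Cuffdiff p under 0.05 these had 6 and 0, 0 and 2, and 0 and 1 members higher and lower.

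**Figure D3:**
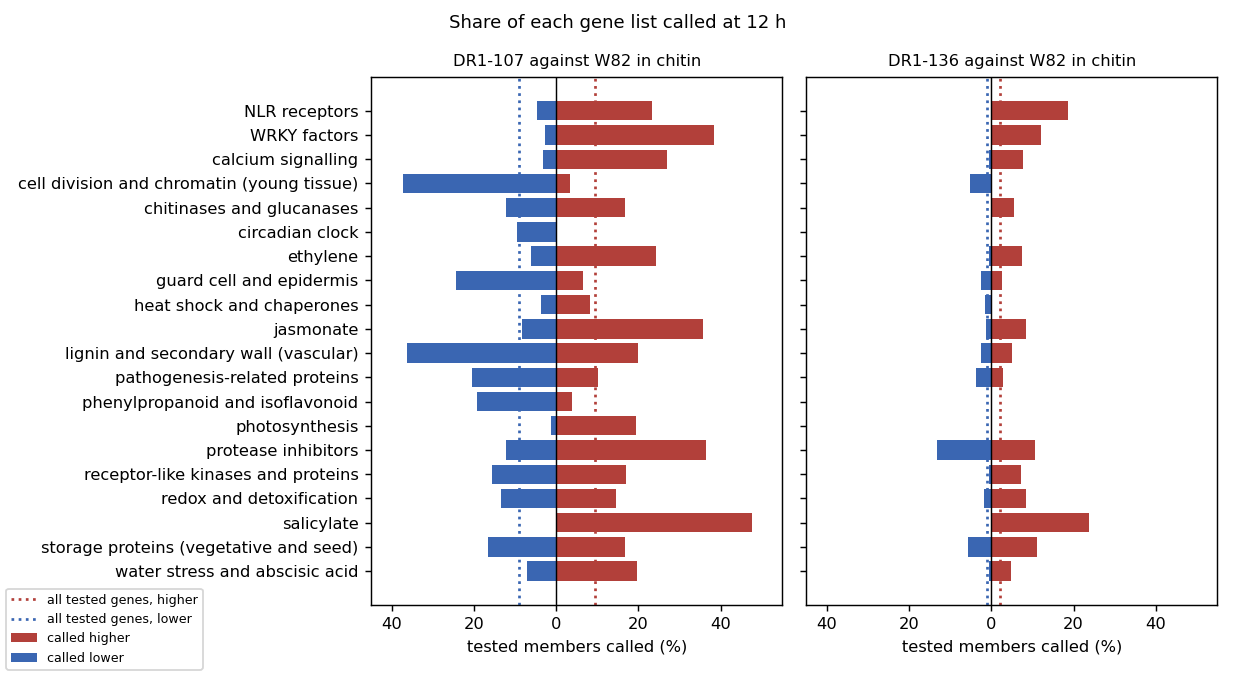
Share of tested members of each gene list called higher (red, right) or lower (blue, left) than W82 in chitin at 12 h, with dotted lines for all tested genes. NLR receptors had 23.2% called higher in the group labelled DR1-107 and 18.6% in the group labelled DR1-136.

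Both transgenic groups in chitin were set against the same W82 samples, and genes called in both mostly moved the same way. The peroxidase Glyma.09G284400 was 6.93-fold higher in DR1-107 and 11.2-fold higher in DR1-136 in the authors' deposited tables. A JAZ gene had log2 changes of 4.28 and 2.77 in the authors' deposited tables. A xyloglucan endotransglucosylase, a wall-remodelling enzyme, had log2 changes of 3.52 and 2.06 in the authors' deposited tables. Shared falls were led by a gamma-thionin gene with log2 changes of -4.30 and -4.18 in the authors' deposited tables. Of 32876 genes tested in both, 734 were called in both and 707 of these had the same direction, 508 higher and 199 lower. Independent lists of these sizes would share 59.9 higher and 29.0 lower genes. Fold changes on the log2(FPKM + 0.1) scale were correlated across 31018 genes, which are not independent replicates, with Pearson's r of 0.592 and Spearman's rho of 0.573. Unchanged groups sharing the controls gave a simulated r of 0.463. The covariance was 0.189 against 0.0815 in the simulation, a difference of 0.107, and would be 0.144 if all error were shared. The controls could not be split, since only 1 value per group is held, so part of the excess may come from the shared controls.

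In the group labelled W82, NLR, receptor-like kinase, cell division and wall genes were over-represented among the genes called higher in chitin than in buffer at 12 h, and heat shock genes among those called lower. AP2/ERF genes (the ethylene list), over-represented among lower calls, were called both ways. W82 in buffer is 1 of the groups that stood apart, with r of 0.659 with W82 in chitin, while DR1-107 in buffer had r of 0.984 with W82 in chitin. Cuffdiff called 11536 of 30480 tested genes in the authors' deposited table, 6469 higher and 5067 lower in chitin. Of these calls 1014 were listed at 0 in buffer and 63 at 0 in chitin. With such genes left out, 5455 were higher and 5004 lower. The largest rises were those of Glyma.06G013200, with an organ-specific protein domain, from 0.257 to 197 FPKM, and of Glyma.02G064300, a T2 ribonuclease, from 0.369 to 248, in the authors' deposited table (Cuffdiff adjusted p = 0.0219 and 0.0352). The largest falls were those of Glyma.18G225300, with a C2 domain, from 228 to 0.364 FPKM, and of Glyma.01G036000, a UDP-glycosyltransferase, from 949 to 2.47, in the authors' deposited table (Cuffdiff adjusted p = 0.0086 and 0.000378). A Kunitz protease inhibitor was 208-fold lower and a gene for a phytosulfokine peptide precursor 306-fold lower in chitin in the authors' deposited table. NLR genes had 66 higher and 13 lower of 171 against a background of 21.2% and 16.6% (adjusted p = 2.48e-06 for higher calls by Fisher's exact test; 71 and 13 adjusted over the list alone). More higher calls by Fisher's exact test were also found for receptor-like kinases (176 and 105 of 526, adjusted p = 9.75e-10), cell division (46 and 11 of 112, adjusted p = 1.69e-05) and lignin (33 and 5 of 71, adjusted p = 2.05e-05). Epidermis (33 and 6 of 73, adjusted p = 2.91e-05), redox (87 and 50 of 266, adjusted p = 8.6e-05) and pathogenesis-related proteins (38 and 24 of 97, adjusted p = 0.00025) followed, by Fisher's exact test. These lists had, adjusted over the list alone, 184 and 107, 46 and 11, 34 and 6, 33 and 7, 94 and 53, and 38 and 25. More lower calls by Fisher's exact test were found for ethylene (55 and 64 of 206, adjusted p = 2.51e-06), heat shock genes (27 and 68 of 261, adjusted p = 0.000493) and calcium (42 and 45 of 180, adjusted p = 0.0153). Protease inhibitors (6 and 13 of 36, adjusted p = 0.0167), WRKY factors (33 and 36 of 139, adjusted p = 0.0179) and water stress (47 and 47 of 200, adjusted p = 0.0357) followed, by Fisher's exact test. Adjusted over the list alone, these had 59 and 68, 25 and 67, 44 and 50, 6 and 13, 36 and 38, and 50 and 47. Several of these lists had medians inside the range of random lists matched on expression, at percentile 90.8 for NLR genes, 70.4 for receptor-like kinases, 33.6 for ethylene, 41.3 for calcium, 34.8 for WRKY and 14.5 for water stress genes. The median log2 change of the ethylene list was 0.18, of the opposite sign to its excess of lower calls. NLR genes had fewer lower calls (adjusted p = 0.00347) and heat shock genes fewer higher calls (adjusted p = 2.91e-05) than the background, by Fisher's exact test. Among calls at adjusted p under 0.01, water stress (adjusted p = 0.233) and the deficit of lower NLR calls (adjusted p = 0.0528) no longer passed Fisher's exact test. Jasmonate (22 and 14 of 68), salicylate (3 and 7 of 20), photosynthesis (7 and 7 of 59) and chitinases and glucanases (18 and 15 of 75) did not pass Fisher's exact test. Nor did phenylpropanoid genes (3 and 7 of 25), storage proteins (6 and 4 of 17) or the clock (3 and 1 of 19). Of these, the jasmonate median (0.23) lay at percentile 98.2 of random lists. The clock list does not hold LHY, a core clock gene peaking around dawn. The 3 copies of LHY analysed here, fixed by identifier, were all called higher in chitin, at 54.5 against 25.5, 8.11 against 2.21 and 4.52 against 1.46 FPKM in the authors' deposited table (Cuffdiff adjusted p = 0.0294, 0.000378 and 0.00338).

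The group labelled DR1-107 in buffer at 12 h differed from W82 in buffer in much the same genes. Of the 30223 genes tested both here and in W82 chitin against buffer, 10778 were called in both, all 10778 in the same direction, with Pearson's r of 0.986 across 29013 genes. Simulated unchanged groups sharing W82 in buffer gave an r of 0.483 and a covariance of 0.538, against an observed covariance of 3.51. Cuffdiff called 12477 of 31050 tested genes in the authors' deposited table, 7031 higher and 5446 lower. Of these calls 1121 were listed at 0 in W82 and 93 at 0 in DR1-107. With such genes left out, 5910 were higher and 5353 lower. The T2 ribonuclease Glyma.02G064300 led the rises with 266 FPKM against 0.366, and a short-chain dehydrogenase, Glyma.11G180800, the falls with 0.188 against 208, in the authors' deposited table (Cuffdiff adjusted p = 0.0242 and 0.0392). NLR genes had 86 higher and 13 lower of 191 against a background of 22.6% and 17.5% (adjusted p = 1.89e-10 for higher calls by Fisher's exact test; 88 and 13 adjusted over the list alone). An NB-ARC gene was at 4.32 FPKM against 0.188, and one that also carries leucine-rich repeats at 0.866 against 40.8, in the authors' deposited table (Cuffdiff adjusted p = 0.00033 for each). More higher calls by Fisher's exact test were also found for receptor-like kinases (205 and 104 of 549, adjusted p = 2.71e-13), lignin (35 and 6 of 73, adjusted p = 1.59e-05) and redox (96 and 46 of 273, adjusted p = 2.05e-05). Epidermis (34 and 6 of 76, adjusted p = 0.000123), pathogenesis-related proteins (38 and 25 of 96, adjusted p = 0.000873) and cell division (42 and 16 of 113, adjusted p = 0.00181) followed, by Fisher's exact test. These lists had, adjusted over the list alone, 219 and 110, 37 and 7, 100 and 51, 34 and 8, 38 and 27, and 43 and 16. Ethylene (61 and 66 of 211, adjusted p = 9.34e-06), heat shock (31 and 72 of 267, adjusted p = 0.000578) and calcium (43 and 51 of 180, adjusted p = 0.00149) had more lower calls by Fisher's exact test. So did protease inhibitors (5 and 14 of 37, adjusted p = 0.0122), WRKY factors (36 and 37 of 140, adjusted p = 0.0282) and water stress (51 and 50 of 207, adjusted p = 0.045), by Fisher's exact test. Adjusted over the list alone, these had 66 and 68, 30 and 71, 44 and 52, 5 and 16, 37 and 39, and 51 and 52. Medians were inside the range of random lists, at percentile 40.4 for ethylene, 21.4 for calcium, 55.9 for WRKY and 42.8 for water stress genes, with log2 changes of 0.18 for ethylene and 0.01 for water stress. As in that comparison, NLR genes had fewer lower calls (adjusted p = 0.00012) and heat shock genes fewer higher calls (adjusted p = 2.91e-05) than the background, by Fisher's exact test. The water stress result did not pass among calls at adjusted p under 0.01 (adjusted p = 0.0669 by Fisher's exact test). Photosynthesis genes had fewer higher calls than the background (5 and 9 of 59, adjusted p = 0.0218 by Fisher's exact test; 2 and 9 adjusted over the list alone). Jasmonate (24 and 12 of 69), salicylate (3 and 4 of 20), chitinases and glucanases (22 and 20 of 80), phenylpropanoid genes (3 and 7 of 25), storage proteins (5 and 4 of 16) and the clock (3 and 1 of 19) passed in neither direction. The medians of jasmonate (0.33) and photosynthesis genes (-0.23) lay at percentile 99.5 and 0.06 of random lists.

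Within the group labelled DR1-107, WRKY, AP2/ERF (the ethylene list) and photosynthesis genes were over-represented among the genes called higher in chitin than in buffer at 12 h. Cell division genes were over-represented among those called lower. Wall genes, over-represented among lower calls, were called both ways. This comparison does not involve W82, but it shares the DR1-107 chitin samples with the comparison against W82 in chitin. Its reference, DR1-107 in buffer, had r of 0.984 with W82 in chitin, and its label is in doubt. Results found in both comparisons are therefore not independent. Cuffdiff called 8053 of 33729 tested genes in the authors' deposited table, 4172 higher and 3881 lower in chitin. The largest rises were those of Glyma.14G145900, with an RCC1 repeat domain, from 0.542 to 35.8 FPKM, and of Glyma.16G153400, a glutamate dehydrogenase, from 0.401 to 21.8, in the authors' deposited table (Cuffdiff adjusted p = 0.000559 for each). An isocitrate lyase gene, whose enzyme is of the glyoxylate cycle, was 45.0-fold higher in the authors' deposited table. The largest falls were those of Glyma.17G080500, a cytochrome P450, from 6.33 to 0.106 FPKM, and of Glyma.15G119100, with a hydrophobic seed protein domain, from 20.1 to 0.607, in the authors' deposited table (Cuffdiff adjusted p = 0.00701 and 0.000559). Against a background of 12.4% called higher and 11.5% lower, WRKY factors had 59 higher and 8 lower of 143 (adjusted p = 2.83e-16 by Fisher's exact test). Ethylene (67 and 21 of 234, adjusted p = 4.85e-10), photosynthesis (30 and 1 of 78, adjusted p = 5.19e-08) and calcium (50 and 5 of 186, adjusted p = 7.6e-07) had more higher calls too, by Fisher's exact test. A photosystem I subunit gene rose from 1.44 to 12.8 FPKM and a WRKY gene from 0.315 to 5.42 in the authors' deposited table (Cuffdiff adjusted p = 0.000559 for each). Protease inhibitors (17 and 8 of 37, adjusted p = 4.51e-06), water stress (52 and 17 of 215, adjusted p = 1.59e-05) and jasmonate (24 and 5 of 73, adjusted p = 2.84e-05) followed, by Fisher's exact test. Higher calls also exceeded the background for salicylate (10 and 1 of 21, adjusted p = 0.000368), NLR genes (44 and 22 of 225, adjusted p = 0.00785) and storage proteins (7 and 3 of 18, adjusted p = 0.0138), by Fisher's exact test. Adjusted over the list alone, these 10 lists had 67 and 9, 71 and 22, 32 and 1, 55 and 7, 17 and 8, 54 and 22, 26 and 6, 10 and 1, 45 and 23, and 7 and 3. Lower calls were more frequent for cell division (5 and 40 of 118, adjusted p = 2.06e-09) and lignin (15 and 31 of 81, adjusted p = 7.45e-09), by Fisher's exact test. So they were for epidermis (10 and 24 of 80, adjusted p = 4.1e-05) and redox (43 and 52 of 288, adjusted p = 0.0041), by Fisher's exact test. Receptor-like kinases (117 and 133 of 634, adjusted p = 4.75e-05 and 1.81e-10) and pathogenesis-related proteins (24 and 25 of 110, adjusted p = 0.0167 and 0.00314) exceeded the background both ways, by Fisher's exact test. Among these lists, medians were inside the range of random lists for receptor-like kinases (percentile 39.7), redox (31.6), storage proteins (52.5), water stress (96.3) and jasmonate (97.3). The median log2 change was 0.04 for redox, of the opposite sign to its excess of lower calls. Heat shock genes had fewer lower calls than the background (38 and 18 of 281, adjusted p = 0.019 by Fisher's exact test), as did calcium (adjusted p = 0.000123) and photosynthesis (adjusted p = 0.00718), and cell division genes had fewer higher calls (adjusted p = 0.0153). Numbers adjusted over the list alone for these 7 lists were 8 and 45, 17 and 38, 13 and 31, 52 and 54, 123 and 152, 28 and 28, and 30 and 16. Among calls at adjusted p under 0.01, storage proteins (adjusted p = 0.147), heat shock genes (adjusted p = 0.0671) and the deficit of higher cell division calls (adjusted p = 0.119) no longer passed Fisher's exact test. Chitinases and glucanases (17 and 15 of 91), phenylpropanoid genes (1 and 5 of 28) and the clock (1 and 4 of 21) did not pass it. The medians of phenylpropanoid genes (-0.47) and of chitinases and glucanases (-0.13) lay at percentile 0.02 and 2.37 of random lists, and that of pathogenesis-related proteins (-0.04) at 2.15.

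In the group labelled DR1-136 in buffer at 12 h, most genes called different from W82 in buffer were listed at 0, and few heat shock genes were called. Of 96 heat shock and chaperone genes, 3 were higher and 2 lower (adjusted p = 0.0114 for higher calls by Fisher's exact test; 3 and 3 adjusted over the list alone). Over the 249 genes of the list with FPKM of at least 1 in either group, tested or not, the median log2 change was -0.22, at percentile 99.9 of random lists matched on expression. This did not set the list apart, since the medians of NLR, receptor-like kinase, epidermis, photosynthesis and protease inhibitor genes lay above all 10000 random lists. Storage proteins were at percentile 99.8, cell division genes at 99.6 and ethylene genes at 0.23. An HSP90-domain gene was at 224 FPKM against 24.9 and an HSP70-domain gene at 149 against 16.2 in the authors' deposited table (Cuffdiff adjusted p = 0.00228 and 0.00684). Glyma.05G065300, an expansin gene, was at 717 against 13.1 FPKM, and the Kunitz inhibitor Glyma.09G163600 at 145 against 3.69, in the authors' deposited table (Cuffdiff adjusted p = 0.0215 and 0.0492). Glyma.13G093800, with B-box and CCT domains, was 13.2-fold lower, and Glyma.02G075100, with a sugar transporter-type domain, was at 26.4 against 207 FPKM, in the authors' deposited table (Cuffdiff adjusted p = 0.031 and 0.0181). Cuffdiff called 414 of 7665 tested genes in the authors' deposited table, 24 higher and 390 lower, and 374 of them were listed at 0 in DR1-136, which had 15738 genes above 0. With genes at 0 in either group left out, 38 calls were left, 22 higher and 16 lower. Cuffdiff called 0 of 15 NLR, 0 of 54 WRKY, 0 of 65 receptor-like kinase, 0 of 29 cell division, 0 of 15 photosynthesis, 0 of 8 clock, 0 of 7 salicylate and 0 of 6 storage protein genes. At an unadjusted Cuffdiff p under 0.05 these lists had 2 and 0, 4 and 2, 6 and 2, 0 and 2, 1 and 0, 0 and 1, 1 and 0, and 0 and 0 members higher and lower. Calls were 0 and 7 of 65 for ethylene, 0 and 5 of 72 for calcium, 0 and 3 of 45 for pathogenesis-related proteins and 0 and 3 of 33 for jasmonate, with 2 and 16, 6 and 6, 4 and 6, and 1 and 4 at an unadjusted Cuffdiff p under 0.05. They were 0 and 2 for chitinases and glucanases (of 21), epidermis (of 23), phenylpropanoid genes (of 11) and water stress (of 60), with 1 and 2, 1 and 2, 0 and 3, and 7 and 4 at an unadjusted Cuffdiff p under 0.05. Redox genes had 2 and 7 of 95, protease inhibitors 1 and 1 of 29 and lignin 0 and 1 of 11. Their numbers were 15 and 10, 4 and 4, and 0 and 3 at an unadjusted Cuffdiff p under 0.05. Among these lists Fisher's exact test was passed only by heat shock genes. The transgenic groups in buffer shared 175 calls of the same direction, 3 higher and 172 lower, where independent lists would share 174. Across 7087 genes their fold changes had a Pearson's r of 0.126 and a Spearman's rho of 0.0737, against an r of 0.274 in simulated unchanged groups sharing W82 in buffer. The covariance was 0.304 against 0.250 in the simulation, and below the 0.346 it would reach if all error were shared.

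The chitin response of the group labelled DR1-107 differed from that of W82 in many genes. WRKY and AP2/ERF genes were over-represented among the higher differences, and NLR and cell division genes among the lower ones. The response was tested per gene as the difference of the genotype changes in chitin and in buffer, with a z test on standard errors implied by the authors' deposited p-values. For DR1-107, 11892 of 29203 genes passed, 5820 with a higher and 6072 with a lower response than W82. This test uses W82 in buffer, which stood apart from DR1-107 in buffer at r of 0.606. WRKY factors had 52 members with a higher and 22 with a lower difference of 133 (adjusted p = 4.26e-06 for higher by Fisher's exact test; 53 and 22 adjusted over the list alone). AP2/ERF genes, the ethylene list, with a median difference of 0.04 on the log2 scale, had 78 and 43 of 194 (adjusted p = 3.53e-09) and protease inhibitors 16 and 5 of 29 (adjusted p = 0.000227), by Fisher's exact test. NLR genes had 22 and 61 of 186 (adjusted p = 0.000624 for more lower and 0.0120 for fewer higher differences by Fisher's exact test). Cell division genes had 12 and 43 of 100 (adjusted p = 6.71e-06 for lower by Fisher's exact test). Among the largest differences were those of a Kunitz inhibitor gene, at 12.53 on the log2 scale with an SE of 3.13, and of Glyma.15G105900, the triose-phosphate transporter gene, at -12.66 with an SE of 4.90. For DR1-136, 6 of 7073 genes passed and 506 had an unadjusted p under 0.05. The median SE was 0.895 for DR1-136 and 0.536 for DR1-107. Of simulated log2 differences of 2, 3.5% and 29% were recovered for these lines. So few calls therefore do not show that DR1-136 responded like W82. With the upper bound of the standard error at the smallest p, an alternative chosen after seeing the data, 0 genes passed. Higher differences were those of a cupin gene (4.07, SE 0.908), a phytosulfokine precursor gene (3.58, SE 0.858) and a UDP-glycosyltransferase gene (3.52, SE 0.844). Lower ones were those of a glutathione S-transferase gene (-4.46, SE 0.980), a Bet v 1-type gene of the PR-10 family (-3.73, SE 0.852) and Glyma.03G058800, without a domain (-7.85, SE 0.883). The last was named after its value was seen.

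At 24 h few genes could be compared, except in the comparisons of DR1-107 in chitin. Genes above 0 numbered 5781 in W82 in buffer, 694 in DR1-136 in buffer, 253 in DR1-107 in buffer, 564 in W82 in chitin, 1015 in DR1-136 in chitin and 34888 in DR1-107 in chitin. A gene without a domain, Glyma.13G011150, took 84.1 to 88.4% of all FPKM in each group at 24 h except DR1-107 in chitin, where it took 4.96 or 5.36%, depending on the table. Scaling also differed between tables. The FPKM of W82 in chitin summed to 1.95e+07 against DR1-136 and to 116814 against DR1-107. That of DR1-107 in buffer summed to 5.87e+06 against W82 and to 74495 against its chitin group. W82 in buffer (1.58e+07 and 1.4e+07) and DR1-107 in chitin (1.9e+06 in both) changed less. Levels and median changes at 24 h therefore depend on the table and may not reflect expression. The letters that the labels give to the 24 h groups also conflict with the way the 24 h tables pair groups, by analogy with 12 h. The labels were kept. In chitin 5 of 14 tested genes were called for DR1-136 against W82, 1 higher and 4 lower, where the median log2 change of expressed genes was -0.38. A mitochondrial ATP synthase subunit gene was at 11057 against 5144 FPKM, and a gene with the domain of photosystem II reaction centre proteins at 96828 against 676991, in the authors' deposited table (Cuffdiff adjusted p = 0.000233 for each). An elongation factor gene was at 1160 against 3839 FPKM, a gene without a domain at 25284 against 82625 and a metallothionein gene was listed at 0 against 101635, in the authors' deposited table (Cuffdiff adjusted p = 0.00543, 0.000233 and 0.0314). In buffer, 7 of 18 tested genes were called for DR1-107 and 4 of 16 for DR1-136 against W82, all listed at 0 in the transgenic group in the authors' deposited tables. Those called for DR1-136 were a Bet v 1-type gene, a potato inhibitor I-type gene, a BURP-domain gene and an extensin gene, at 2819 to 3521 FPKM in W82 in the authors' deposited table. Cuffdiff called 7676 of 13680 tested genes in DR1-107 against W82 in chitin and 7600 of 13163 in DR1-107 chitin against buffer in the authors' deposited tables. All were higher and against a group listed at 0, so no fold is given. The median log2 change of expressed genes, which depends on the scaling of the table, was 5.64 over 204 genes in the first and 4.61 over 113 genes in the second. At adjusted p under 0.01 Cuffdiff's counts were 0 and 0, with 8044 and 7904 at an unadjusted p under 0.05. In these tables NLR genes were called in 18 of 63 and 19 of 62 tested members, and WRKY genes in 58 of 87 and 59 of 84. Chitin against buffer in W82 and DR1-136 at 24 h, and in DR1-136 at 12 h, was not analysed here.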

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

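Of the tests below, those of sampling error, of a single dominant gene and of exchanged labels were chosen after the result was seen. So was the use of LHY and GIGANTEA beside the clock list. The difference of chitin response was tested per gene with a z test on the authors' deposited p-values, and by list with Fisher's exact test. It passed for 11892 of 29203 genes in DR1-107 against W82 and for 6 of 7073 in DR1-136 against W82. These counts do not compare the lines, since few differences could be found for DR1-136. Of simulated log2 differences of 2, 3.5% were recovered for DR1-136 and 29% for DR1-107. In DR1-107 the response was higher more often than in other genes for 52 of 133 WRKY factors, 78 of 194 ethylene, 56 of 172 calcium, 68 of 258 heat shock, 21 of 66 jasmonate, 19 of 59 photosynthesis, 16 of 29 protease inhibitor, 11 of 20 salicylate genes and 56 water stress genes. Adjusted over the list alone the numbers were 53, 80, 58, 68, 23, 19, 17, 11 and 59. It was lower more often for 61 of 186 NLR, 43 of 100 cell division, 27 of 63 epidermis, 26 of 62 lignin, 34 of 89 pathogenesis-related, 157 of 505 receptor-like kinase and 76 of 247 redox genes. Counts adjusted over the list alone were 62, 44, 27, 26, 37, 163 and 80. Receptor-like kinases also had more higher differences (121, adjusted p = 0.0491), and heat shock genes (35, adjusted p = 0.0102) and photosynthesis genes (5, adjusted p = 0.0371) fewer lower ones, by Fisher's exact test. Chitinases and glucanases (18 higher and 17 lower of 74), clock (2 and 5 of 19), phenylpropanoid (5 and 3 of 25) and storage protein genes (4 and 3 of 15) passed in neither direction.

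Most of this rests on W82 in buffer, which with DR1-136 in buffer stood apart from DR1-107 in buffer and the chitin groups. Sampling error of the shared W82 buffer libraries, of the size implied by the authors' p-values, is argued against. The covariance of the 2 comparisons against them was 3.51 (bootstrap SE 0.0427, 29013 genes), above the bound of 1.01 if all error were shared. This bound comes from the same p-values that called the genes, so it adds little beyond those calls. The bootstrap treats genes as independent. A different hour of harvest stays undecided, since the clock genes gave differing results. The 19 clock genes of the list had a median absolute change in W82 at percentile 9.63 of random lists. This met the preset bound against a different hour. That list had lost LHY, and all 3 LHY genes were called higher in chitin than in buffer in the authors' deposited table. GIGANTEA, a clock gene also fixed by identifier, was not called there. It was at 83.7 FPKM in chitin against 69.6 in buffer in the authors' deposited table (log2 0.27). A smaller share of mesophyll cells stays undecided, with 3 of 4 marker lists of other cell types above the random lists, 0 below and photosynthesis at percentile 29.6. In DR1-107 against W82 in chitin, cell division, lignin and epidermis medians lay at percentile 0, storage proteins at 20.3 and photosynthesis at 100. In the chitin response of DR1-107 these were the same but for storage proteins, at 52.5. In both, photosynthesis and 3 of the 4 other lists lay on opposite sides of the random lists. A different share of mesophyll cells could give this pattern. It was preset as a test only for the chitin response of W82. For these comparisons of DR1-107 the explanation was not tested and stays open, also for their cell division and wall results. Also open, and untested, are a library batch, a wrong label of DR1-107 in buffer and a chitin-like state of that line without chitin, which could each give the r of 0.984 between DR1-107 in buffer and W82 in chitin.

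At 24 h all groups but DR1-107 in chitin had few genes above 0. A single gene taking most of the FPKM is argued against as the whole cause. Without that gene, the lowest listed share was still 29.9 to 125 times that of DR1-107 in chitin. Low depth may account for it but stays undecided, since the genes above 0 had median ranks at 12 h from percentile 87.0 to 89.8, under the preset bound of 90 and far above the bound that would have excluded it. No biological explanation was tested.

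GmDR1 was called lower in the group labelled DR1-107 in chitin than in the group labelled W82 at 12 h, and for DR1-136 the difference did not pass the test. Exchanged labels of the W82 and DR1-107 chitin groups, an explanation found and tested on the same data, stay undecided. The group labelled W82 in chitin had an r with DR1-107 in buffer that was 0.0633 above that of the group labelled DR1-107 in chitin, and the latter had an r with W82 in buffer that was 0.0543 above that of the former. DR1-136 in chitin, which such an exchange leaves in place, showed the same orders by 0.0540 and 0.0480, so the test is not specific to an exchange, and it rests on DR1-107 in buffer, whose own label is in doubt. Regulation of the native gene by chitin stays open and untested, and the labels were kept.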

How the results depend on the processing

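Alternatives with FPKM of at least 10 and with the upper bound of the standard error were chosen after seeing the data. Of the alternative values of counts, overlaps and correlations, 106 stayed, 34 moved and 0 reversed. Counts stayed if within 1.5 times, and shares and correlations if inside their confidence interval. Counts and overlaps could not reverse under this rule. Some values could hardly move, such as 11 recomputed adjustments, the sign of GmDR1 and correlations after centring. Of those of single lists and named genes, 413 stayed, 55 became weaker and 8 stronger. Weaker means a lost call or a list median back inside the range of random lists. Named genes were picked for large changes, so all 75 stayed at an absolute log2 change of at least 1. At adjusted p under 0.01 the calls at 12 h were 3791 for DR1-107 and 533 for DR1-136 against W82 in chitin, 7536 for chitin in W82 and 5184 for chitin in DR1-107, and at 24 h 0 for DR1-107 against W82 in chitin and 0 for its chitin response. At that threshold 1 list was over-represented among lower calls of DR1-136 in chitin, the pathogenesis-related proteins (adjusted p = 0.00706 by Fisher's exact test, against 0.0559 before), while both lists called before were lost. It left 1 gene for its response difference, and overlaps of 359 in chitin and 105 in buffer. An absolute log2 change of at least 1 gave 3783 calls for DR1-107 against W82 in chitin, 4657 for its chitin response and an overlap of 402. Genes with FPKM of at least 10 in both groups gave 3233 and 37 calls for DR1-107 and DR1-136 in buffer, 2222 and 415 in chitin, and 3065 and 2813 for the chitin response of W82 and DR1-107. In all 4 groups that minimum gave response differences of 3371 for DR1-107 and 3 for DR1-136, from fewer genes tested. With genes at 0 left out, DR1-136 in buffer at 12 h had 38 calls, and at 24 h DR1-107 in buffer, DR1-136 in buffer, DR1-107 in chitin and its chitin response each had 0. No filter for the median put fewer lists above random lists than the main setting, 5 for DR1-107 and 5 for DR1-136 in buffer. It put more lists below, 3 for DR1-136 in buffer, 7 for DR1-136 in chitin and 6 for chitin in W82. A pseudocount of 1 put 3 below for DR1-136 in buffer, also more than the main setting. It gave a correlation of 0.601 in chitin against 0.592, a small shift that lies outside an interval made narrow by treating genes as independent. With the upper bound of the standard error the response difference of DR1-136 had 0 genes. Beyond fewer genes tested and the zeros left out, the cause was not tested. Median centring moved the split of higher and lower calls by under the preset limit in every comparison. No paired analysis was possible because the tables used here give 1 value per group, and for that reason leaving out replicates, the replicate block, count-based tests, a pseudocount per replicate and other splits of the samples were not run. What depth limits was not measured, since read depth is unknown from FPKM.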

Other observations

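The following scan of Pfam domains was chosen after the data were seen. It covered 834 domains with at least 10 genes in the chitin comparisons of DR1-107 and DR1-136 with W82 and in the chitin response of DR1-107, all at 12 h, and 360 of 4942 tests passed with Fisher's exact test. Genes with the TIR domain, which many NLRs also carry, were called higher in 25 of 103 members in DR1-136 (adjusted p = 3.77e-17), 29 of 101 in DR1-107 (adjusted p = 2.27e-06) and 26 of 106 in the chitin response of DR1-107 (adjusted p = 0.0108), by Fisher's exact test. The domain of xyloglucan endotransglucosylases, which remodel cell walls, was called higher in 23 of 38 genes in DR1-107 (adjusted p = 3.23e-12) and 7 of 38 in DR1-136 (adjusted p = 0.000358), by Fisher's exact test. NAC transcription factors were higher in 34 of 119 genes in DR1-107 (adjusted p = 2.41e-07 by Fisher's exact test). The domains of trehalose-phosphate synthase (11 of 16, adjusted p = 1.25e-06) and trehalose-phosphatase (15 of 30, adjusted p = 1.3e-06), of trehalose synthesis, were also higher in DR1-107, by Fisher's exact test. A gene was counted under every domain it carries, so these results may share genes. Fisher's exact test treats genes as independent here too.

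Lower in DR1-107 in chitin were 48 of 126 UDP-glycosyltransferases (adjusted p = 5.6e-16), 44 of 108 kinesins (adjusted p = 6.32e-16), 11 of 12 genes with the MCM domain of the replicative helicase (adjusted p = 5.61e-09) and 15 of 32 tubulins (adjusted p = 2.09e-06), by Fisher's exact test. Expansins (18 of 53, adjusted p = 2.53e-05) and SWEET sugar transporters (8 of 22, adjusted p = 0.00942) were lower there as well, by Fisher's exact test. In DR1-136, 10 of 128 UDP-glycosyltransferases (adjusted p = 3.03e-05) and 4 of 22 SWEET transporters (adjusted p = 0.00159) were lower, by Fisher's exact test. Within DR1-107, chitin went with lower calls of 55 of 108 kinesins (adjusted p = 1.83e-20) and 54 of 129 UDP-glycosyltransferases (adjusted p = 1.22e-15), by Fisher's exact test. A different share of mesophyll cells stays open for these comparisons of DR1-107.

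Of 12 identifiers of isoflavone synthase, chalcone synthase, clock and PR1 genes fixed from knowledge before the data were examined, 11 are in the tables. In the authors' deposited tables Cuffdiff called 3 higher and 1 lower in DR1-107 in buffer, 0 and 3 in DR1-107 in chitin, 3 and 1 in the chitin response of W82 and 2 and 3 in that of DR1-107. The 3 copies of LHY made up all 3 higher calls in DR1-107 in buffer and in the chitin response of W82, and all 3 lower calls in DR1-107 in chitin and in its chitin response. For DR1-136 Cuffdiff called 0 in either treatment, with 0 higher and 1 lower in buffer and 0 and 0 in chitin at an unadjusted p under 0.05.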
